A study of Mus musculus with 4 samples.

How the data were processed

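The deposited matrices hold integer UMI counts per gene and barcode, which the authors made with Cell Ranger, and no further step before deposit is given per the labels. Per the submitters' processing notes the tools were Cell Ranger 3.0.2, R 4.1.1 and Seurat 4.0.2 with genome build mm9, while the feature identifiers matched the GRCm38 annotation. The headers of both 4-week matrices name Cell Ranger 6.1.1 and those of the 24-week matrices name no software, so the ages may come from different pipelines. Of 32287 features, 32285 had Ensembl identifiers, 32158 of which were in the annotation, 31436 with the same symbol, and the other 2 were the reporters EYFP and GFP. Whether intronic reads were counted is not stated. The groups, the gene lists, the comparison, the rule for named genes and most alternatives were chosen before the data were examined. Xist was nearly absent and Uty present in all libraries, so the groups do not differ in sex.

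Barcodes with fewer than 300 genes or over 5% mitochondrial UMIs were left out. Scrublet scored doublets, but its own threshold marked almost none, so the 8% of barcodes with the highest score were left out in each library, a share chosen after the scores were seen. This left 9200, 9196, 9247 and 11293 nuclei in the vehicle library and the library labelled KO at 4 weeks and then at 24 weeks, 38936 in all. Counts were normalised, log-transformed, scaled per gene and reduced to 25 components of 3000 variable genes, and Leiden clustering with 30 neighbours at resolution 1.0 gave 35 clusters. A cluster was named from marker genes where at least 3 markers were detected, the score reached 0.8 and led the next class by 0.3. It also had to hold 100 nuclei, with a median doublet score of at most 0.15. A cluster stayed unnamed too where 3 or more of its top 10 genes were on a list of free RNA genes. The same held where those genes held more markers of another class than its own, or where depth was low without an own marker. Cluster 16, which scored highest for club, was left unnamed by the free RNA rule and cluster 32 by the marker rule. These thresholds were set after the clusters were seen, and 28 clusters with 33519 nuclei were named. In all, 6 embeddings were run with class counts in view, and 1 was taken because it looked stable. On another random subsample stability did not favour it, with adjusted Rand indices of 0.964 between seeds and 0.937 under subsampling against 0.966 and 0.943 for Pearson residuals with 30 neighbours, which left 4418 nuclei unnamed against 5417. It was not replaced once gene results were known, and the other 5 serve as alternatives.

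Counts were summed per class and library, and classes with at least 50 nuclei in both libraries were compared. The log2 ratio of CPM used 0.5 added counts, and its 95% interval is the exact conditional interval for a ratio of 2 Poisson counts. Genes needed 30 UMIs over the 2 libraries. Where a count was 0 the fold was computed with 3 counts in its place. This leaves out the counting error of the other count, so the lower end of the log2 interval is given beside it. Arhgef7 is always named. Other genes were ranked by the interval bound nearest 0, leaving out mitochondrial, ribosomal protein and sex-linked genes, unnamed gene models, and genes whose level in the class was under 10% of that in the class where they were highest. The top 10 each way are named in AT2-like nuclei and the top 5 in other classes, and from each list up to 4 members with the largest bound, except that some genes and a further list are not used here. Members of a list count as higher or lower at 1.5-fold by size only. Each list median was placed among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries, because random lists hold genes that do not vary together. In AT2-like nuclei AT2 identity lay at percentile 0.3 and 0.0 at 4 and 24 weeks. AT1 identity in AT1-like nuclei lay at 9.0 and 0.0 and capillary genes in aCap-like nuclei at 6.2 and 0.8, and in gCap-like nuclei at 24 weeks at 16.5, so 3 of these medians lie within the random range. An alternative for free RNA subtracts, per library, the lowest level of each gene among the classes with at least 200 nuclei.

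The interval was tested on simulated data with known ratios. With the counts of AT2-like nuclei at 4 weeks it held the true ratio for 95.6% of 9620 unchanged genes, 95.6% of 91 with a 2-fold and 96.6% of 89 with a 4-fold difference, and it left out 0 for 84.6% of the 2-fold genes. At 24 weeks it held the true ratio for 96.2% of 9895 unchanged genes, 97.8% of 93 and 94.4% of 89, and it left out 0 for 87.1% of the 2-fold genes. The simulation covers counting error and not variation between mice. Work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.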

Results

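Nuclear RNA of mouse lung was sequenced from single nuclei in 4 libraries. Per the labels, the mice either lacked βPIX, the protein of the gene Arhgef7, in alveolar type 2 (AT2) epithelial cells, which make surfactant, or were vehicle controls. βPIX is a guanine nucleotide exchange factor that localises to focal adhesions. Lungs were taken at 4 and 24 weeks, and the labels do not say from which event the weeks count. Each of the 4 groups, vehicle and labelled KO at each age, holds 1 library, so there are no replicates, no difference was tested, and every statement describes these libraries. The deposited matrices hold 10000 barcodes for the vehicle library and 10000 for the library labelled KO at 4 weeks, and 10053 and 12276 at 24 weeks. Their total counts were 17031496, 15843393, 20538705 and 26151808 UMIs in the same order, with medians of 1365, 1283, 1462 and 1405 UMIs per nucleus. Although the labels give AT2 cells as the cell type, the nuclei fell into epithelial, endothelial, mesenchymal and immune classes of whole lung. Intervals in square brackets are 95% intervals that cover counting error only, and log2 ratios are of counts scaled to the UMI total of the class (CPM) in the library labelled KO over the vehicle library of the same age.

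The targeted gene was not lower in AT2-like nuclei of the libraries labelled KO. Arhgef7 (ENSMUSG00000031511; GRCm38 chromosome 8, 11727721 to 11835219, plus strand, a gene of 107499 bp with 13 annotated transcripts) stood at 78.9 [64.1, 96.0] CPM in AT2-like nuclei of the vehicle library at 4 weeks and at 104 [90.1, 120] in the library labelled KO. At 24 weeks the levels were 77.8 [63.6, 94.3] and 103 [88.6, 120]. The log2 ratios were 0.40 [0.05, 0.76] at 4 weeks and 0.41 [0.05, 0.77] at 24 weeks. Over the alternatives they ranged from 0.13 with classes from own markers to 1.69 with free RNA subtracted at 4 weeks, and from 0.22 to 0.52 at 24 weeks. After each nucleus was thinned to 1000 UMIs, 6.87% [5.24, 8.81] of AT2-like nuclei of the vehicle library and 9.56% [7.87, 11.5] of those of the library labelled KO had an Arhgef7 UMI at 4 weeks, and 8.36% [6.29, 10.8] and 9.76% [7.71, 12.1] at 24 weeks. Thinning left out 81 and 493 shallower nuclei at 4 weeks and 222 and 251 at 24 weeks, and the shares without thinning were 9.77%, 11.2%, 11.4% and 15.6%, at median depths of 1202, 1076, 1322 and 1473 UMIs. No class could serve as one that lacks the gene, since Arhgef7 was read in every class, with alveolar fibroblast-like nuclei at 130 to 183 CPM and aCap-like (aerocyte) nuclei at 139 to 181. The higher level at 24 weeks was not particular to AT2-like nuclei. It was 0.50 [0.24, 0.77] in AT1-like, 0.39 [0.18, 0.61] in alveolar fibroblast-like and 0.45 [0.08, 0.84] in alveolar macrophage-like nuclei, and 0.28 [0.18, 0.38] over all kept nuclei. At 4 weeks the log2 ratio was 0.24 in alveolar fibroblast-like, 0.29 in alveolar macrophage-like, -0.26 in AT1-like and -0.59 in club-like nuclei, and -0.07 over all kept nuclei. The labels do not give the deleted exons, so reads from the rest of the gene check nothing, and the groups are called libraries labelled KO throughout. Neither a swapped label nor an injury that the labels leave out can be excluded, and either would change what each ratio means.

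**Figure D1:**
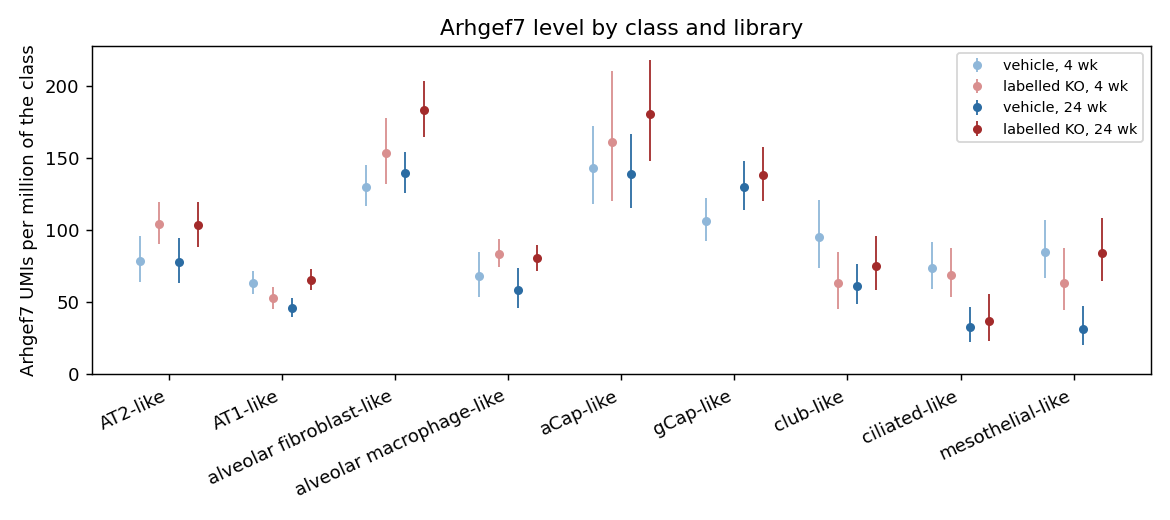
Arhgef7 level (CPM, vertical axis) in each class in each library, with points for the level and bars for the exact 95% Poisson interval of the count. In AT2-like nuclei both libraries labelled KO (104 and 103) lie above both vehicle libraries (78.9 and 77.8). At 24 weeks the library labelled KO was also higher in AT1-like (65.5 against 46.2), alveolar fibroblast-like (183 against 139) and alveolar macrophage-like nuclei (80.6 against 58.8).

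The makeup of the lung differed between the libraries of each age. Among the classes compared at both ages the largest difference was in alveolar macrophages, the resident phagocytes of the air spaces. Alveolar macrophage-like nuclei made up 6.73% [6.23, 7.26] of kept nuclei in the vehicle library and 23.4% [22.6, 24.3] in the library labelled KO at 4 weeks, a ratio of 3.48. At 24 weeks they made up 5.74% [5.28, 6.24] and 15.4% [14.8, 16.1], a ratio of 2.69. Of those in the 4-week library labelled KO, 88.8% lay in cluster 1, whose median doublet score was 0.131. Alveolar fibroblast-like nuclei made up 17.1% and 8.06% at 4 weeks and 14.7% and 8.04% at 24 weeks, and aCap-like nuclei, of the capillary endothelium that lines the gas exchange surface, 5.65% and 2.53% at 4 weeks and 5.50% and 2.96% at 24 weeks. AT2-like nuclei made up 9.90% and 17.1% at 4 weeks and 9.0% and 8.76% at 24 weeks. The 4-week difference in AT2-like nuclei was not firm, since its log2 value of 0.79 ranged from 0.08 at clustering resolution 2.0 to 2.59 at resolution 0.5, and the 24-week log2 value of -0.04 became 0.63 with classes from own markers. The shares of aCap-like and alveolar fibroblast-like nuclei at 4 weeks also rest on the clustering, because they had log2 values of -1.16 and -1.09 that became -5.90 with no nuclei left out as doublets and -5.91 with centred log values and 20 neighbours. AT1-like nuclei made up 20.9% and 20.1% at 4 weeks and 15.04% and 11.7% at 24 weeks. T-like nuclei made up 0.696% and 0.979% at 4 weeks and 2.30% and 3.53% at 24 weeks.

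Sums of marker genes over all kept nuclei, which need no clustering, went the same way for alveolar macrophages, alveolar fibroblasts and aCap, but not for AT2 at 4 weeks. The 12 alveolar macrophage markers summed to 613 and 2111 CPM in the vehicle library and the library labelled KO at 4 weeks, and to 849 and 2457 at 24 weeks, ratios of 3.44 and 2.89. The corresponding ratios were 0.607 and 0.642 for alveolar fibroblast markers, 0.493 and 0.583 for aCap markers and 0.511 and 0.697 for gCap (general capillary) markers. They were 0.853 and 0.866 for AT2 markers. Markers of activated fibroblasts had ratios of 1.39 and 1.64, those of the transitional epithelial state 1.93 and 1.49, and those of proliferating cells 1.95 and 2.15. Of the nuclei, 2.91% and 10.6% at 4 weeks and 15.1% and 24.6% at 24 weeks lay in 7 clusters that stayed unnamed. Cluster 3, led by Retnla, Spp1 and Apoe, held 16.6% of the 24-week library labelled KO, cluster 16, led by Bpifa1 and Scgb3a1 of the airway, 11.8% of the 24-week vehicle library, and cluster 18, in which gCap markers led only narrowly, 7.85% of the 4-week library labelled KO. With cluster 18 unnamed, 10 nuclei of that library were gCap-like against 17.01% of the vehicle library, so gCap-like nuclei were not compared at 4 weeks. This count rests on the clustering, since both embeddings of Pearson residuals gave 704 and 705 gCap-like nuclei in that library. The barcodes of the 4-week libraries start at 906 UMIs or more and those of the 24-week libraries at 500, so differences between the ages include how barcodes were selected.

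**Figure D2:**
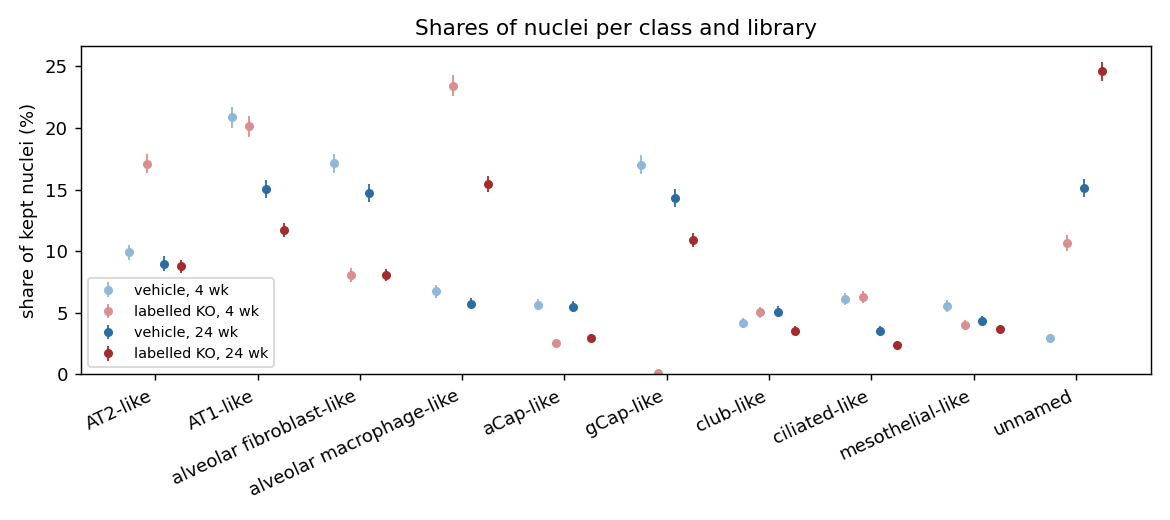
Share of kept nuclei (percent, vertical axis) in each class for the 4 libraries, with points for the share and bars for the exact 95% binomial interval. Alveolar macrophage-like nuclei stand at 23.4% and 15.4% in the libraries labelled KO against 6.73% and 5.74% in the vehicle libraries.

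The next comparison asks how AT2 cells, the cells named as the site of the deletion, differed at 4 weeks. In AT2-like nuclei of the library labelled KO, the median of surfactant and AT2 identity genes was lower and that of genes of the damage-associated transitional state was higher. The AT2 identity list had a median log2 ratio of -0.58 [-0.68, -0.53], with 8 of 18 measured genes at least 1.5-fold lower and 3 at least 1.5-fold higher. The transcription factor Etv5 had a log2 ratio of -1.33, the phosphate transporter Slc34a2 -1.05, the complement gene Hc -1.0 and the chemokine gene Cxcl15 -1.09. The transitional list, genes that AT2 cells turn on when they repair damage, had a median of 1.21 [0.85, 1.45], with 12 of 15 genes higher and 0 lower, among them the TGF-beta-activating integrin subunit Itgb6 at 1.70, the urokinase receptor gene Plaur at 1.89, the galectin gene Lgals3 at 1.49 and clusterin, Clu, at 2.13. Plaur and Lgals3 stood in AT2-like nuclei at 41.5% and 48.1% of their level in the class where each was highest. The clusters of the 4 libraries differed, since cluster 20 held 97.7% of the AT2-like nuclei of the 4-week vehicle library, cluster 10 97.2% of those of the library labelled KO, and clusters 23 and 17 97.8% and 98.9% of those of the 24-week vehicle library and the library labelled KO. Cluster 10 was the most weakly named, with an AT2 score of 1.15 and ciliated next at 0.73, against AT2 scores of 1.85 to 2.78 in the others. Its median doublet score was 0.136, against 0.052 to 0.077. The 12 markers that name AT2 clusters are all on the identity list, so a mixed cluster would also have a lower identity median. The AT2 identity median shrank to -0.25 with classes from each nucleus's own markers, to -0.26 with at most 1 percent mitochondrial UMIs and to -0.28 with no doublets left out.

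Other lists in AT2-like nuclei at 4 weeks went both ways. Targets of p53 and senescence genes had a median of 0.58 [0.40, 0.99], with 8 of 17 genes higher and 2 lower, among them the autophagy regulator Trp53inp1 at 1.37, Gdf15 at 2.19 and the pro-apoptotic gene Bax at 1.22. That median was 1.78 once free RNA was subtracted. The list of YAP/TAZ targets and the Hippo pathway had a median of -0.75 [-0.91, -0.53], with 10 of 16 genes lower. Even so Ccn2, a direct YAP target, had a log2 ratio of 2.33 and Axl 1.65, beside Vgll3 at -3.67 and Vgll4 at -1.16. Vgll3 had 4 UMIs against 37, at 19.7% of its level in alveolar fibroblast-like nuclei, where it was highest. It was also lower there (-3.08) and in ciliated-like (-5.76) and mesothelial-like (-2.49) nuclei. Lipid and cholesterol synthesis had a median of -0.50 [-0.63, -0.18], with Acoxl at -2.74, Acly at -0.98 and Acaca at -0.63 but the lipid regulator Pparg at 1.69, and the median was -0.10 among genes with at least 100 UMIs. Antigen presentation and interferon genes had a median of 0.64 [0.43, 1.07], with H2-K1 at 1.19 and B2m at 1.44, and 0 of 13 genes were lower. Medians were 0.69 over 6 cell cycle genes (0.22 to 1.40 over the alternatives), 0.66 for immediate-early genes, 0.27 for collagens and matrix, 0.24 for focal adhesion and cytoskeleton, 0.23 for TGF-beta signalling, 0.16 for secretory factors of senescence and 0.11 for the unfolded protein response. With classes from own markers collagens stood at 0.003 and focal adhesion at 0.009, and secretory factors stood at -0.23 with at most 1 percent mitochondrial UMIs. Medians were -0.05 for AT1 identity (-0.51 to 0.39 over the alternatives), -0.11 for Wnt/beta-catenin targets, -0.34 for Wnt pathway components and -0.38 for epithelial junctions. The median of all 9851 genes measured was -0.12.

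Of the 10 genes named as higher in AT2-like nuclei of the 4-week library labelled KO, 8 were at their highest in alveolar macrophage-like nuclei. These were the macrophage elastase Mmp12 (286 UMIs against 8, log2 4.46 [3.55, 5.77]), Lilr4b (4.08), the scavenger receptors Marco (4.50, 121 UMIs against 3 [3.14, 7.02]) and Msr1 (3.87), the cystine transporter Slc7a11 (3.79), Cd300lf (3.15), Mmp19 (66 UMIs against 2, 4.12 [2.52, 7.51]) and Kynu (3.03). The metallothionein gene Mt2 (91 UMIs against 1, log2 5.32 [3.38, 11.2]) was highest in mesothelial-like nuclei, and the lipocalin gene Lcn2 (3.65 [2.93, 4.59]) in AT2-like nuclei. The 10 genes named as lower were Acoxl (-2.74 [-2.93, -2.56]), the lysozyme gene Lyz1 (-3.26), Vgll3 (-3.67), Unc5d (-2.94), Tmem132d (-2.25), Auts2 (-2.24), Bmp6 (-2.20), Tspan7 (-2.17), Txlng (-2.07) and Bex2 (-3.09). With classes from each nucleus's own markers Marco stood at 2.45, Mmp19 at 2.18 and Unc5d at -1.90, with centred log values and 20 neighbours Bmp6 at -1.13 and Tspan7 at -1.40, and with free RNA subtracted Slc7a11 at 7.49. Acoxl, Lyz1, Tmem132d and Bex2 were highest in AT2-like nuclei. Vgll3 was highest in alveolar fibroblast-like, Unc5d in pericyte-like, Auts2 in aCap-like and Txlng in club-like nuclei. Bmp6 and Tspan7 were highest in gCap-like nuclei, a class nearly unnamed in the 4-week library labelled KO.

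At 24 weeks, AT2-like nuclei of the library labelled KO again had a lower median of surfactant and AT2 identity genes, and a higher median of p53 targets. The AT2 identity median was -0.52 [-0.56, -0.42], with 8 of 20 genes lower and 2 higher. Surfactant protein C, Sftpc, had a log2 ratio of -1.13, Slc34a2 -0.80, Etv5 -0.82 and Hc -0.76. The lower Sftpc was not particular to AT2-like nuclei. In the vehicle library and the library labelled KO it stood at 891 and 498 CPM in AT1-like and at 1297 and 795 in alveolar fibroblast-like nuclei. Senescence genes and p53 targets had a median of 0.80 [0.42, 1.01], with 10 of 19 genes higher and 2 lower, among them the cell cycle inhibitor Cdkn1a at 2.01, Trp53inp1 at 1.82 and the stress sensor Sesn2 at 1.40. That median was 0.29 with classes from each nucleus's own markers, 0.39 after thinning and 1.27 with free RNA subtracted. The transitional list had a median of 0.53 [0.38, 0.74], with 6 of 16 genes higher and 1 lower, and Itgb6 at 1.15, Clu at 1.26, Tnip3 at 1.68 and Tm4sf1 at -1.04. Lipid and cholesterol synthesis had a median of -0.60 [-0.76, -0.27], with Acoxl at -2.18 and Hmgcs1 at -0.94 beside Pparg at 1.41 (9.5% of its highest level by class), and was -0.21 among genes with at least 100 UMIs.

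The Wnt lists bear on the Wnt/beta-catenin signalling that the series design names. Wnt/beta-catenin targets had a median of -0.57 in AT2-like nuclei at 24 weeks, with 5 of 10 genes lower and 2 higher, among them the feedback inhibitors Znrf3 at -1.22 and Rnf43 at -0.82, and Notum at -1.71, beside Ccnd1 at 0.91. The direction turned under 2 alternatives, with a median of 0.46 among genes with at least 100 UMIs and 0.40 after thinning. At 4 weeks the list had a median of -0.11, with 2 of 8 genes lower and 2 higher, Znrf3 at -1.35 and Rnf43 at -1.26 beside Cd44 at 0.75 and Ccnd1 at 0.67. Wnt pathway components had a median of -0.19 at 24 weeks. The YAP/TAZ and Hippo list had a median of -0.40 [-0.56, -0.20] at 24 weeks, with Amotl2 at -1.22 and Frmd6 at -0.99 beside the tissue factor gene F3 at 1.51. Antigen presentation had a median of 0.84, with Tap1 at 1.90 and H2-Ab1 at 1.24. Medians of the other lists at 24 weeks were 0.99 for 9 cell cycle genes (0.25 at clustering resolution 2.0), 0.56 for collagens and matrix, 0.36 for focal adhesion, 0.21 for TGF-beta signalling, -0.04 for immediate-early genes, -0.06 for the unfolded protein response (0.22 with free RNA subtracted), -0.13 for secretory factors (0.34 with own markers), -0.33 for AT1 identity and -0.38 for junctions (-0.07 and -0.08 with Pearson residuals and 20 neighbours). The median of all 10154 genes measured was -0.07.

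**Figure D3:**
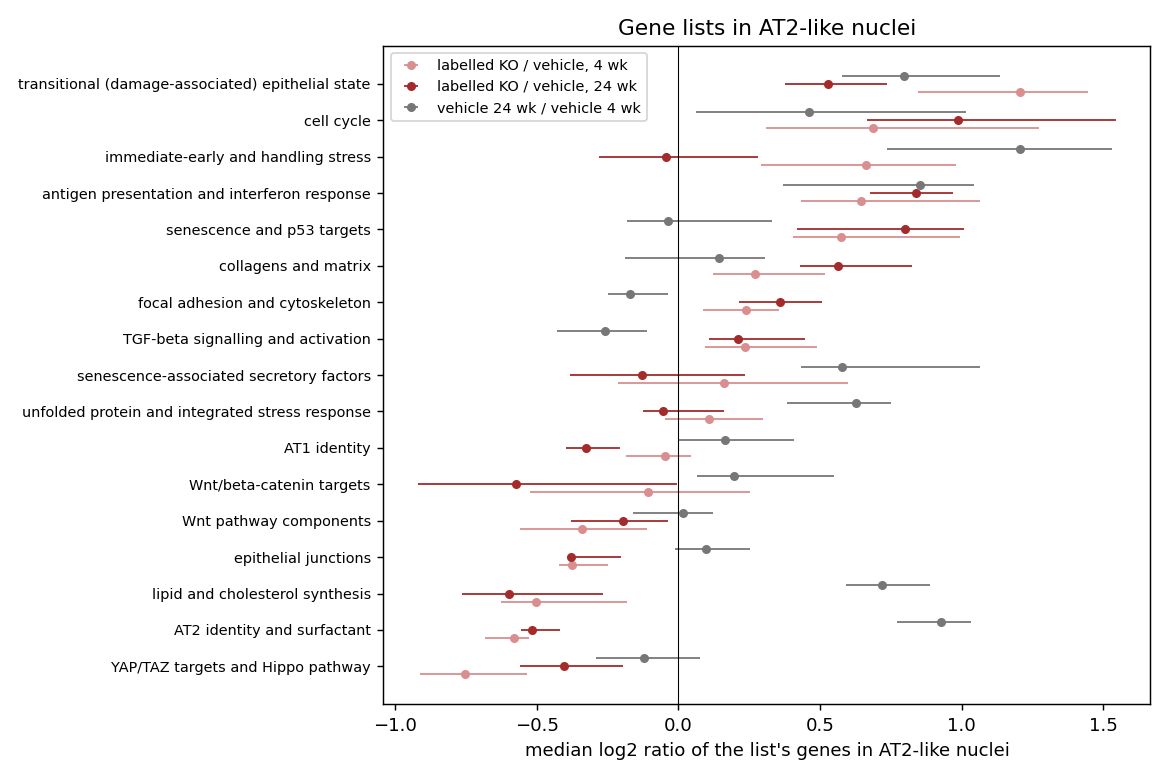
Median log2 ratio (horizontal axis) of each gene list in AT2-like nuclei for the library labelled KO over vehicle at each age and for vehicle at 24 over 4 weeks, with bars for the 95% range over Poisson draws of the counts. AT2 identity lies at -0.58 and -0.52 in the libraries labelled KO and at 0.93 between the vehicle libraries.

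Among the 10 genes named as higher in AT2-like nuclei at 24 weeks, 5 were highest in AT2-like nuclei. These were Psrc1, a spindle and p53-responsive gene with 49 UMIs against 0 (12.8-fold higher with 3 counts in the vehicle library, lower log2 bound 3.33), the arginase gene Arg2 (3.44 [2.82, 4.21]), Malt1 (3.05 [2.81, 3.30]), Pde1c (3.53) and Corin (57 UMIs against 2, 4.17 [2.56, 7.56]). Mmp12 (4.01) and Slc7a11 (3.83) were highest in alveolar macrophage-like nuclei. Spp1 (osteopontin, 3.37) was highest in pericyte-like nuclei, nearly tied with alveolar macrophage-like nuclei (453.2 and 449.9 CPM in the library labelled KO). The glucocorticoid-responsive Fkbp5 (3.43) was highest in mesothelial-like nuclei and Mt2 (3.55) in alveolar fibroblast-like nuclei. The 10 genes named as lower were Bpifa1 (-2.81, an airway gene highest in club-like nuclei), Acoxl (-2.18), Tmem132d (-2.13), Lyz1 (-2.31), Auts2 (-2.11), Pon1 (-3.11), Fbn2 (-2.82), Inmt (-2.09), Agbl1 (-2.31) and Ttn (-2.05). Of these 10, 5 were highest in AT2-like nuclei, while Auts2 was highest in aCap-like, Pon1 in club-like, Inmt in alveolar fibroblast-like and Agbl1 in B-like nuclei. Agbl1 turned direction under 3 alternatives, with values of 0.16 to 1.004. Several of these genes rest on the classes, because with own markers Psrc1 stood at 1.51, Pde1c at 0.61, Corin at 2.31, Mt2 at 2.06, Pon1 at -1.35, Fbn2 at -1.35, Auts2 at -1.39 and Ttn at -1.0. Fkbp5 stood at 5.25 with free RNA subtracted.

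Ratios at 4 and 24 weeks went together across genes in AT2-like nuclei. Over 9234 genes, Pearson's r was 0.673 and Spearman's coefficient 0.594, and 71.8% of genes had the same sign; genes are not independent replicates. The r was 0.68 in AT1-like, 0.689 in alveolar fibroblast-like and 0.579 in alveolar macrophage-like nuclei, and also 0.407 in ciliated-like, 0.523 in club-like and 0.512 in mesothelial-like nuclei, classes that are not the site of the deletion. With free RNA subtracted, r in AT2-like nuclei was 0.199 and Spearman's coefficient 0.265 over 8671 genes, 425 of which then had a log2 ratio beyond 5. At 400000 UMIs per class sum, the median absolute log2 ratio in AT2-like nuclei was 0.42 at 4 weeks and 0.36 at 24 weeks, against 0.36 between the vehicle libraries of the 2 ages and 0.21 to 0.22 for counting noise. Malat1, a nuclear RNA, took 8.96% and 13.4% of UMIs at 4 weeks and 4.91% and 6.79% at 24 weeks in the vehicle libraries and the libraries labelled KO, and Gm42418, a gene that overlaps ribosomal RNA, 2.71% and 6.21%, and 1.48% and 3.46%.

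The vehicle libraries of the 2 ages differed by as much as several of these lists did. In AT2-like nuclei, the 24-week over 4-week vehicle medians were 0.93 for AT2 identity, 0.80 for the transitional list, 0.85 for antigen presentation, 0.72 for lipid synthesis and 1.21 for immediate-early genes. They were -0.04 for senescence and p53 targets, -0.12 for the YAP/TAZ and Hippo list and -0.17 for focal adhesion. The matrix headers name software for the 4-week libraries only, so different pipelines may add to differences between the ages. The 4-week vehicle library enters both this comparison and that with the 4-week library labelled KO.

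AT1 cells, the thin gas exchange epithelium that AT2 cells renew, were compared next. AT1-like nuclei of both libraries labelled KO had a higher median of transitional genes and a lower median of AT1 identity genes. The transitional list had medians of 1.04 [0.83, 1.26] at 4 weeks, with 13 of 16 genes higher and 0 lower, and 0.77 [0.50, 0.92] at 24 weeks, with 9 of 16 higher and 2 lower. Itgb6 had log2 ratios of 1.29 and 1.44, the stress-induced Sfn 2.16 and 1.66 and Tnip3 2.19 and 2.73. AT1 identity genes had medians of -0.38 [-0.41, -0.32], with 6 of 18 genes lower and 1 higher, and -0.53 [-0.58, -0.48], with 8 of 18 lower and 1 higher. At 4 weeks that median lay within the range of matched random lists. Members included the caveola gene Cav1 at -1.98 and -1.76, the transcriptional regulator Hopx at -0.96 and -1.04 and the water channel gene Aqp5 at -0.83 and -1.09, while Pdpn was higher at 4 weeks (1.19). Between the vehicle libraries of 24 and 4 weeks the transitional list differed by 0.78 and AT1 identity by 0.70. The 4-week median of AT1 identity was -0.20 without the 20 most abundant genes in the total and -0.21 with the median of ratios, and the median of all genes in AT1-like nuclei was -0.17 and -0.12.

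TGF-beta signalling genes in AT1-like nuclei had medians of 0.27 [0.08, 0.42] and 0.37 [0.32, 0.48], with Tgfbi at 2.43 and 2.39 and Pmepa1 at 1.63 and 1.32. At 24 weeks Tgfbi stood in AT1-like nuclei at 6.5% of its highest level by class, and the 4-week median was -0.11 with free RNA subtracted. The YAP/TAZ and Hippo list had medians of -0.68 and -0.41 (-0.22 at 24 weeks after thinning). At 4 weeks Ankrd1 stood at 2.15 and Ccn2 at 1.74, against Vgll3 at -2.90. Vgll3 was highest in alveolar fibroblast-like nuclei of the vehicle library and was lower there too (-3.08). Focal adhesion genes stood at 0.09 and 0.33, with the actinin genes Actn1 at 1.17 and 1.01 and Actn4 at 1.09 and 0.81, and the 4-week median was -0.07 after thinning. Medians at 4 and 24 weeks were 0.20 and 0.40 for senescence and p53 targets (0.04 at 24 weeks with free RNA subtracted), 0.70 and 0.82 for antigen presentation (0.17 at 24 weeks with free RNA subtracted) and 0.28 and 0.34 for lipid synthesis. Wnt/beta-catenin targets stood at -0.93 and 0.31 (-0.75 at 24 weeks with free RNA subtracted), Wnt pathway components at -0.42 and -0.15, and junctions at -0.22 and -0.16. Secretory factors stood at 0.05 and 0.27 (-0.33 at 4 weeks among genes with at least 100 UMIs and -0.50 at 24 weeks with free RNA subtracted), the unfolded protein response at 0.00 and -0.11 (-0.43 at 4 weeks with free RNA subtracted), and cell cycle genes at 0.74 and 0.32 (-0.66 at 4 weeks with free RNA subtracted). Collagens stood at -0.10 and 0.90 (-0.09 at 24 weeks with free RNA subtracted). Cluster 2 held 99.2% of the AT1-like nuclei of the 4-week vehicle library, cluster 4 96.6% of those of the library labelled KO, and clusters 11 and 12 95.2% and 95.5% of those at 24 weeks.

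The genes named as higher in AT1-like nuclei at 4 weeks were the heme oxygenase gene Hmox1 (4.08), Arg1 (63 UMIs against 2, 4.82 [3.22, 8.21]), Psrc1 (58 against 2, 4.71 [3.10, 8.09]), Mmp12 (3.60) and Lilr4b (3.39), of which 4 were highest in alveolar macrophage-like nuclei and Psrc1 in AT2-like nuclei. At 24 weeks they were Fbxw10 (4.56), highest in AT1-like nuclei, Ms4a6d (44 UMIs against 0, 13-fold higher with 3 counts in the vehicle library, lower log2 bound 3.34), Zbtb16 (3.42), Fkbp5 (3.48) and Hmox1 (3.56). Those named as lower were Lyz1 (1 UMI against 37, -4.49 [-10.4, -2.49]), Mkks (1 against 36, -4.45 [-10.4, -2.44]), Sox11 (-3.59), Acoxl (-2.54) and Igfbp6 (-2.92) at 4 weeks. At 24 weeks they were the airway gene Scgb3a2 (-2.32), the neurotrophin gene Bdnf (-2.16), highest in AT1-like nuclei, G0s2 (-3.20), Tppp3 (-2.02) and Smad9 (-2.31). Of the 5 named as lower at 4 weeks, 0 were highest in AT1-like nuclei, and Lyz1 and Acoxl were highest in AT2-like nuclei. Acoxl was also lower at 4 weeks in ciliated-like (-1.85), mesothelial-like (-1.81) and club-like (-2.24) nuclei. With free RNA subtracted, Arg1 stood at 2.75, Sox11 at -2.39 and Igfbp6 at -4.61 at 4 weeks. At 24 weeks Fbxw10 stood at 7.49, Zbtb16 at 6.01, G0s2 at -0.90 and Tppp3 at -3.23. Under that subtraction too few UMIs were left for a value of Hmox1, Mmp12, Lilr4b and Acoxl at 4 weeks. The same held for Hmox1 and Scgb3a2 at 24 weeks. With own markers Lyz1 stood at -2.0 at 4 weeks.

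Alveolar fibroblasts were compared because the series design concerns collagen and fibrosis. In alveolar fibroblast-like nuclei of both libraries labelled KO, the medians of matrix genes and of genes of the activated fibroblast state were higher. The activated fibroblast and myofibroblast list had medians of 1.40 [1.01, 1.71] at 4 weeks, with 8 of 13 genes higher and 3 lower, and 1.53 [1.07, 2.08] at 24 weeks, with 10 of 13 higher and 1 lower. Its members included the acute-phase gene Saa3 (52 UMIs against 1 at 4 weeks, log2 6.28 [4.31, 12.2], and 5.62 at 24 weeks), Spp1 (3.54 and 3.73), the metalloproteinase inhibitor gene Timp1 (3.81 and 4.32) and, at 4 weeks, Lcn2 (4.81). Spp1 was not particular to these nuclei, since at 24 weeks its level in the library labelled KO was 286 CPM here and 313 in AT2-like nuclei. The 4-week median was 0.54 with classes from own markers, and the medians were 2.28 and 3.05 with free RNA subtracted. Collagens and matrix genes had medians of 0.51 [0.42, 0.67] and 0.98 [0.79, 1.10], with 10 of 23 and 15 of 24 genes higher, and 2 and 1 lower. Tenascin C, Tnc, had log2 ratios of 3.84 and 3.90 and the latent TGF-beta binding protein gene Ltbp2 3.14 and 3.56, with fibronectin, Fn1, at 1.73 at 4 weeks and the proteoglycan gene Vcan at 2.37 and the basement membrane gene Col4a2 at 1.95 at 24 weeks. The fibrillar collagen genes Col1a1 and Col3a1, picked after their values were seen, stood at 0.56 and 0.49 at 4 weeks and 0.69 and 0.80 at 24 weeks. The collagen median at 4 weeks was 0.21 with classes from own markers. Between the vehicle libraries of 24 and 4 weeks the activated list differed by 0.41 and the collagen list by 0.33.

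Lists other than matrix in alveolar fibroblast-like nuclei had medians at 4 and 24 weeks of 0.57 and 0.33 for senescence and p53 targets (0.05 at 24 weeks with free RNA subtracted), 0.34 and 0.60 for secretory factors (-0.03 at 4 weeks with own markers), with the chemokine gene Cxcl10 at 3.79 at 24 weeks, and 0.87 and 0.69 for antigen presentation, with Nlrc5 at 2.30 and 2.13. TGF-beta signalling stood at 0.08 and 0.32 (-0.31 and 0.06 with free RNA subtracted), with Tgfbi at 2.97 and 1.61. Wnt pathway components stood at -0.01 and -0.03, although Sfrp1, a Wnt antagonist, had log2 ratios of 2.01 and 3.38 and Rspo3 3.06 at 24 weeks, and Wnt/beta-catenin targets at -0.28 and -0.35. Cell cycle genes stood at 1.03 at 24 weeks (2.84 with free RNA subtracted), with Top2a at 2.67 and Mki67 at 2.87. The genes named as higher at 4 weeks were the fibrillar collagen gene Col11a1 (37 UMIs against 0, 27.4-fold higher with 3 counts in the vehicle library, lower log2 bound 4.40), Mt2 (5.18), Saa3, the adhesion gene Chl1 (4.71) and Csmd1 (3.95), and at 24 weeks Chl1 (5.41), Saa3, the activin antagonist Fst (57 UMIs against 0, 27.7-fold higher with 3 counts in the vehicle library, lower log2 bound 4.45), Kif26b (4.79) and Tnc. Those named as lower were Colq (-3.43), Vgll3 (-3.08), Gria1 (-2.53), Smim4 (-2.84) and Sox11 (1 UMI against 51, -3.95 [-9.85, -1.98]) at 4 weeks, and Igfbp3 (-3.20), Bpifa1 (-3.33), G0s2 (-3.08), Tnnt2 (-3.41, and -1.22 to -1.74 under 4 alternatives) and Colq (-2.77) at 24 weeks. With own markers Chl1 stood at 3.0 and Sox11 at -2.52 at 4 weeks. Cluster 8 held 96.5% and 92.1% of these nuclei in the libraries labelled KO, and clusters 7 and 14 98.4% and 91.0% in the vehicle libraries of 4 and 24 weeks. The median of all genes was -0.11 and -0.08.

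Alveolar macrophages were compared as the class with the largest difference in its share among those compared at both ages. In alveolar macrophage-like nuclei of the libraries labelled KO, the median of genes linked to repair and fibrosis was higher, and so was Arg1, the arginase of alternatively activated macrophages. Arg1 had 289 UMIs against 0 at 4 weeks, 30.3-fold higher with 3 counts in the vehicle library (lower log2 bound 4.615), and 560 against 2 at 24 weeks, a log2 ratio of 6.15 [4.61, 9.52]. The profibrotic macrophage list had medians of 0.69 [0.58, 0.85], with 11 of 20 genes higher and 3 lower, and 0.24 [0.17, 0.36], with 7 of 20 higher and 1 lower. Spp1 had log2 ratios of 3.35 and 3.03 and Mmp12 2.95 and 2.67, with cathepsin K, Ctsk, at 1.20 at 4 weeks and Apoe at 1.38 at 24 weeks. The Spp1 ratio was as large in other classes at 24 weeks, at 3.70 in ciliated-like, 4.37 in mesothelial-like and 3.39 in club-like nuclei, so it is not particular to macrophages. The 24-week median was 0.11 with free RNA subtracted and 0.09 at clustering resolution 0.5, and the list differed by 0.84 between the vehicle libraries of 24 and 4 weeks.

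The other genes named as higher in alveolar macrophage-like nuclei at 4 weeks were Tmem267 (5.16), the complement gene C1qb (94 UMIs against 0, 9.86-fold higher with 3 counts in the vehicle library, lower log2 bound 2.975), Lcn2 (170 against 2, 4.42 [2.87, 7.80]) and Retnla (130 against 1, 4.78 [2.85, 10.7]), and at 24 weeks Atf7ip2 (4.12), Slc36a2 (3.96), Adam8 (3.83) and Spp1. Among named classes, Lcn2 was highest in AT2-like, Retnla in club-like, Slc36a2 in alveolar fibroblast-like and Adam8 in ciliated-like nuclei. C1qb was highest in T-like nuclei (90 in the 4-week library labelled KO) and Spp1 in pericyte-like nuclei. Both were near ties with alveolar macrophage-like nuclei, so these rankings do not show another source. In the 24-week library labelled KO, Spp1 stood at 449.9 CPM in alveolar macrophage-like, 453.2 in pericyte-like and 507.5 in unnamed nuclei. With free RNA subtracted Tmem267 stood at 10.2 and Slc36a2 at 7.57, and Atf7ip2 stood at 6.43 after thinning. Those named as lower at 4 weeks were Cpne5 (-4.56), Tmem229a (-4.28), Cdc42ep3 (-2.51), the peroxisomal thiolase Acaa1b (-2.52) and AI504432 (-2.39), each highest in alveolar macrophage-like nuclei. At 24 weeks they were Bpifa1 (-3.77), Cpne5 (-3.29), Slc9a2 (-3.52), Acaa1b (-2.63) and Ddx43 (-3.18). Medians at 4 and 24 weeks were 0.69 and 0.39 for antigen presentation (-0.29 at 24 weeks with free RNA subtracted), 0.26 and -0.12 for senescence and p53 targets, -0.01 and -0.01 for lipid synthesis, -0.07 and -0.11 for the unfolded protein response and -0.16 and -0.31 for cell cycle genes. With own markers the lipid median at 4 weeks was 0.18 and that of senescence and p53 targets at 24 weeks 0.13. Cluster 28 held 86.4% of these nuclei in the 4-week vehicle library and cluster 1 88.8% in the library labelled KO. Cluster 0 held 89.3% and 87.1% in the 24-week vehicle library and the library labelled KO. Cluster 1 was the most weakly named macrophage cluster, with a score of 1.43 against 1.73 to 2.29 in the others. Its median doublet score was 0.131, against 0.064 to 0.086. The main AT1-like cluster of the 4-week library labelled KO, cluster 4, also stood high, at 0.119. The median of all genes was -0.14 and -0.09.

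Capillary endothelium was compared last, as aCap-like nuclei at both ages and gCap-like nuclei at 24 weeks. In aCap-like nuclei of both libraries labelled KO the median of capillary genes was lower and that of antigen presentation genes higher. The capillary list had medians of -0.36 [-0.53, -0.18] at 4 weeks, with 5 of 14 genes lower and 3 higher, and -0.39 [-0.56, -0.23] at 24 weeks, with 6 of 16 lower and 1 higher. The endothelin receptor gene Ednrb had log2 ratios of -1.22 and -1.14, with the angiopoietin receptor gene Tek at -1.57 at 4 weeks, and the peptide hormone gene Apln at -2.0, the prostaglandin-degrading Hpgd at -0.76 and the carbonic anhydrase gene Car4 at -0.69 at 24 weeks. The 4-week median lay within the range of matched random lists, and was -0.14 with free RNA subtracted and -0.20 with the median of ratios. In gCap-like nuclei at 24 weeks the list had a median of -0.17 [-0.43, -0.09], with 8 of 20 genes lower, among them Plvap at -1.75, Hpgd at -1.08 and Tek at -0.95, and it ranged from -0.41 to -0.13 over the alternatives. Antigen presentation stood at 0.79 and 0.72 in aCap-like nuclei (0.26 at 24 weeks with free RNA subtracted) and at 0.84 in gCap-like nuclei, with Nlrc5 at 1.41 and the class II regulator Ciita at 1.47 in the latter. Immediate-early genes stood at 0.37 and 0.14 (-0.60 at 24 weeks with free RNA subtracted) in aCap-like and 0.27 in gCap-like nuclei. Between the vehicle libraries of 24 and 4 weeks the capillary list had larger medians in size, 0.65 in aCap-like and 0.93 in gCap-like nuclei.

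Of the 5 genes named as higher in aCap-like nuclei at 4 weeks, Mmp12 (4.60), Tgfbi (3.94), Lilr4b (3.65), Hmox1 (3.99) and Cd300lf (3.52), each was highest in alveolar macrophage-like nuclei. At 24 weeks they were Retnla (3.57), Lilr4b (3.62), Fkbp5 (2.99), Spp1 (2.75) and Mmp12 (3.39), and in gCap-like nuclei Retnla (3.60), Fkbp5 (3.50), Spp1 (3.37), Mmp12 (3.76) and Saa3 (4.08), each highest in another class. Those named as lower in aCap-like nuclei were St13 (-2.81), Kansl2 (3 UMIs against 65, -2.98 [-5.50, -1.58]), Cse1l (1 against 41, -3.54 [-9.45, -1.55]), Rassf9 (-2.58) and Tspan12 (-2.22) at 4 weeks, and the co-chaperone gene Stip1 (-3.31), Bpifa1 (-2.98), Scgb3a2 (-2.12), Dynll1 (-2.22) and P4ha1 (-2.04) at 24 weeks. With classes from own markers Kansl2 stood at -0.25 and St13 at -0.69. With free RNA subtracted St13 stood at -4.76 and Tgfbi at 6.83 at 4 weeks, and Stip1 at -4.99, Dynll1 at -6.38 and P4ha1 at -6.14 at 24 weeks. Too few UMIs of Fkbp5 were left at 24 weeks for a value under that subtraction. Those named as lower in gCap-like nuclei were Bpifa1 (-2.71), Plekhh3 (2 against 33, -3.55 [-6.96, -1.88], and -1.69 with centred log values), Hs3st1 (-2.34), Maoa (-2.16) and Prickle1 (-1.87). Few genes named as lower were highest in their own class, with 1 of 5 in aCap-like nuclei at 4 weeks, 0 of 5 at 24 weeks and 2 of 5 in gCap-like nuclei. Cluster 26 held 99.4% and 97.9% of aCap-like nuclei of the vehicle library and the library labelled KO at 4 weeks, cluster 22 99.4% and 94.6% at 24 weeks, and clusters 13 and 15 98.1% and 99.8% of gCap-like nuclei at 24 weeks. The median of all genes was -0.14 and -0.08 in aCap-like nuclei and -0.04 in gCap-like nuclei.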

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

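No test was run, so the differences here are values of single libraries. The median of immediate-early and handling stress genes in AT1-like nuclei differed between the ages by -0.72, from 0.42 [0.28, 0.80] at 4 weeks to -0.29 [-0.48, -0.03] at 24 weeks in the libraries labelled KO over vehicle. The median of secretory factors of senescence in alveolar macrophage-like nuclei differed between the ages by 0.77, from -0.40 [-0.61, -0.17] to 0.37 [0.16, 0.73]. In each pair the negative median lay within the range of matched random lists, at percentile 10.4 for immediate-early genes at 24 weeks and 7.3 for secretory factors at 4 weeks. EYFP, a reporter that the labels do not mention, had 14, 13, 15 and 81 UMIs in kept nuclei of the vehicle library and the library labelled KO at 4 weeks and then at 24 weeks, and stood at 3.59 [2.85, 4.46] CPM in the 24-week library labelled KO against 0.835 in the vehicle library.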

How the results depend on the processing

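All 16 main results kept their direction under every alternative that gave a value. Of their 288 values, 251 stayed near the reported one and 37 moved, and of 4817 values of 272 other results 15 turned direction; the cause was not tested. This counts genes and shares with an interval that left out 0, and lists with a median outside the range of matched random lists. For the others, 125 values of 34 results changed sign, 90 of them inside the reported interval. No paired analysis was possible within an age because each group has 1 library, and the ages were not used as pairs. The other 5 embeddings, the other seed and the shared UMI minimum were chosen after seeing the data, and 2 added counts, the higher gene minimum, seed 2 and 40 components moved no main result. No value came from aCap capillary genes at 4 weeks with no doublets left out, from Arhgef7, AT2 identity and agreement of the ages in AT2-like nuclei at resolution 0.5, from alveolar fibroblasts at 4 weeks with centred log values and 20 neighbours, or from gCap at 24 weeks with centred log values and 30 neighbours. With counts this shallow, low genes rest on few UMIs.

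AT2 identity at 4 weeks became -0.26 with at most 1 percent mitochondrial UMIs, -0.74 and -0.71 with centred log values and 20 or 30 neighbours, -0.25 with own markers, -0.42 without the 20 most abundant genes, -0.68 with free RNA subtracted, -0.46 with the median of ratios, -0.28 with no doublets left out and -0.39 at resolution 2.0. At 24 weeks it became -0.61 and -0.63 with Pearson residuals and 20 or 30 neighbours, -0.57 with own markers and -0.60 with free RNA subtracted. The correlation between the ages in AT2-like nuclei became 0.69 with Pearson residuals and 30 neighbours, 0.653 with at most 1 percent mitochondrial UMIs, 0.695 with own markers, 0.635 after thinning, 0.199 with free RNA subtracted, 0.77 with at least 100 UMIs and 0.653 with no doublets left out. Arhgef7 in AT2-like nuclei at 4 weeks became 1.69 with free RNA subtracted. Collagens in alveolar fibroblast-like nuclei became 0.21 and 0.76 at 4 and 24 weeks with own markers and 0.38 and 0.69 after thinning. The transitional list in AT1-like nuclei at 4 weeks became 0.78 after thinning, and aCap capillary genes at 4 weeks -0.14 with free RNA subtracted. Profibrotic genes in alveolar macrophage-like nuclei became 0.49 and 0.11 at 4 and 24 weeks with free RNA subtracted, and at 24 weeks 0.17 with Pearson residuals and 20 neighbours and 0.09 at resolution 0.5. The log2 share of alveolar macrophages at 4 weeks became 1.60 with Pearson residuals and 30 neighbours, 1.66 with the shared UMI minimum, 1.62 with centred log values and 20 neighbours, 2.16 with own markers and 1.65 at resolution 2.0, and at 24 weeks 1.57 with the shared UMI minimum.

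Directions turned with own markers for Agbl1 at 24 weeks (1.004) and TGF-beta genes at 4 weeks (-0.012) in AT2-like nuclei, and for the lymphatic share at 24 weeks (-0.10). Agbl1 also became 0.23 at resolution 0.5 and 0.16 with 40 components. With free RNA subtracted they turned for TGF-beta (-0.11) and cell cycle (-0.66) genes at 4 weeks and collagens (-0.089) at 24 weeks in AT1-like nuclei, and for antigen presentation in alveolar macrophage-like nuclei at 24 weeks (-0.29). Wnt targets in AT2-like nuclei at 24 weeks became 0.40 after thinning and 0.46 with at least 100 UMIs, and focal adhesion genes in AT1-like nuclei at 4 weeks -0.067 after thinning. Shares at 4 weeks turned for B-like nuclei with centred log values (0.42 and 1.32 with 20 and 30 neighbours) and for gCap-like nuclei at resolution 0.5 (5.28).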

Other observations

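Of the tests below, those of scaling, of free RNA shared by every class or at the same level in each, of loss of nuclei and of shallow barcodes were chosen only after the result was seen, and the glucocorticoid list was written after 3 of its genes had been seen.

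Immune, airway and nerve markers were also summed over all kept nuclei, whether or not a cluster was named for them. Interstitial macrophage markers had ratios of 1.52 and 1.80 at 4 and 24 weeks in the libraries labelled KO over vehicle, dendritic cell markers 1.58 and 1.66 and T cell markers 1.18 and 1.35. Other immune lists were lower or mixed, with B cell markers at 0.505 and 0.807, innate lymphoid (ILC2) markers at 0.609 and 0.724 and mast cell or basophil markers at 0.644 and 0.765. NK cell markers stood at 0.898 and 0.834, monocyte markers at 0.996 and 1.23, neutrophil markers at 1.34 and 1.01 and plasma cell markers at 1.03 and 1.09. Schwann cell and neuron markers had ratios of 0.469 and 0.620, and cardiomyocyte markers 0.593 and 0.482. These sums need not measure the cells they are named for. The Schwann list holds Scn7a, also a marker of alveolar fibroblasts. The cardiomyocyte list holds Ttn, which among named classes of the 24-week vehicle library was highest in AT2-like nuclei. In the 4-week vehicle library the ILC2 markers summed to 792 CPM, more than the 613 of the alveolar macrophage markers. Club cell markers, of the secretory airway epithelium, had ratios of 0.686 and 0.328, and ciliated cell markers 0.953 and 0.510. Erythroid markers had ratios of 0.846 and 0.421. The airway gene Scgb1a1 stood at 623 and 409 CPM at 4 weeks and at 8440 and 2883 CPM at 24 weeks in the vehicle library and the library labelled KO.

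Macrophage transcripts such as Mmp12, Marco and Lilr4b were higher in AT2-like nuclei of the libraries labelled KO. Scaling by the median of ratios moves values too little to account for this, since the median of all genes was -0.12 and -0.07 at 4 and 24 weeks. With so small a shift, the median log2 ratio of 4.03 under that scaling was fixed in advance. With the lowest level of any class subtracted, the median over 10 values was 4.57 (Mmp12 4.65, Lilr4b 5.23 and Marco 4.50 at 4 weeks). The 10 values are of 8 genes, since Mmp12 and Slc7a11 enter at both ages. The subtraction does not exclude free RNA shared by every class. Free RNA could take a larger part of the UMIs in shallower classes, and the ratio of what is left can stay large. Free RNA could account for the pattern, since these genes had a median of 3.34 over 23 values in ciliated-like, mesothelial-like and club-like nuclei, against 3.94 in AT2-like nuclei. A test of whether AT2-like nuclei hold more of these transcripts than free RNA brings gave 9 of 10 values above its bound. It decides nothing, because at 4 weeks only 2 reference genes were left and the genes were picked for the pattern. Macrophage nuclei within the AT2-like clusters, doublets (cluster 10 had a median doublet score of 0.136, against 0.052 to 0.077 in the other AT2-like clusters) and expression by AT2 cells themselves stay open.

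Alveolar macrophage-like nuclei had larger shares in the libraries labelled KO. Loss of nuclei outside the ciliated-like, club-like, T-like and macrophage classes is excluded as the whole cause, because it would raise these shares alike, while the ratio of alveolar macrophage shares lay above those of the other 3 in 6 of 6 comparisons. Shallow barcodes are excluded too, because with the shared UMI minimum the lower of the log2 ratios was 1.57. More macrophages in the tissue and uneven recovery of nuclei by class, with loss from every class but macrophages, both remain possible, and 1 library per group cannot separate them from differences between mice.

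Fkbp5, Zbtb16 and Mt2, genes that glucocorticoids induce, were higher in several classes of the libraries labelled KO. Glucocorticoid-responsive transcription might underlie this, since a list of 15 other such genes reached the top end of matched random lists in 11 of 11 comparisons, with medians of 0.90 and 1.06 in AT2-like nuclei at 4 and 24 weeks. The same list did so in 5 of 6 comparisons of vehicle at 24 over 4 weeks, so it also separates libraries that share a label. The 11 comparisons are of classes within the same libraries and so are not independent, and 8 to 15 of the 15 genes were measured in them. Free RNA is undecided, with 70.1% of the median log2 ratio of the genes kept after subtraction, and 79.4% when 3 of 32 values left empty are set aside. Stress or handling of single mice and an effect of the deletion stay open alike.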
